A study of Mus musculus with 12 samples.

How the data were processed

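RNA-seq was analysed from 12 libraries of mouse splenic B cells, 3 in each of 4 groups: wild-type (WT) and CHD4 knockout (KO) cells, unstimulated (0 hr) or after 48 hr with 10 µg/ml LPS and 25 ng/ml IL-4. Per the labels' protocols, RNA was extracted with TRIzol and an RNeasy kit, cDNA was made with a SMART-Seq kit, libraries were made with a KAPA Hyper kit, and paired ends were sequenced. The kit does not record strand. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

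The file analysed holds 1 estimated count per transcript and library, as deposited by the authors in whole numbers. Per the submitters' processing notes, the authors used bcl2fastq 2.20.0.422, trimmed reads with Trimmomatic 0.36, quantified transcripts of the mm10 build with Salmon 0.8.2, and used DESeq2 1.14.1. Salmon shares reads among similar transcripts, so values of near-identical genes are uncertain.

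Counts of 63759 transcripts were summed to 32699 gene symbols, after trailing spaces were removed from 344 names. Totals per library were 39 M to 53.2 M (median 51.1 M). Genes were filtered by edgeR's filterByExpr, which left 19125. Libraries were scaled by the trimmed mean of M values (TMM), with factors of 0.723 to 1.42. CPM values use these scaled library sizes. All libraries were fitted together as 4 groups with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, 8 residual degrees of freedom, common dispersion 0.0534). The contrasts were KO against WT at 0 hr and at 48 hr, 48 hr against 0 hr within each genotype, and the interaction. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene was called at an adjusted p below 0.05. No covariate or pairing was used.

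Of 39 gene lists written before the data were examined, 38 had at least 3 tested members. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated from the data, and with fry. Members were counted over all genes and also adjusted over the list alone. Overlap of calls was tested with a one-sided Fisher's exact test. The genes named were set by a rule fixed with the lists: Chd4 and 9 standing genes, the called genes with the largest changes in each direction among those at 5 CPM or more in the higher group without overlap between libraries (no overlap rule for the interaction), and the called members of lists. Genes named outside the rule are stated as chosen after their values were seen. Positions are from GENCODE M21 on mm10.

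A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio with an exact interval. Those intervals cover counting error only, since reads copied by PCR were not removed with molecular tags. Figures were drawn with matplotlib 3.10.9.

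The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 56% and 78% of them at 0 hr, 51% and 74% at 48 hr, 44% and 86% over time in WT, 55% and 81% over time in KO, and 27% and 61% in the interaction. False calls made up 6.94%, 4.58%, 3.7%, 2.86% and 5.38% of the calls. Apart from the changed genes, each simulated gene had the same mean and the same spread in all 4 groups. In the real data edgeR's biological coefficient of variation ran from 14.3% (WT 48 hr) to 31.1% (KO 0 hr). There 14138 of 19125 genes changed over time in WT, so these rates may not hold for the real contrasts.

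Alternatives were DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, relative log expression and upper-quartile scaling, TMM without immunoglobulin, mitochondrial and ribosomal genes, no low-count filter, at least 1 CPM in 3 libraries, dispersion estimated without the robust option, separate fits of the libraries of each contrast, a 2-fold minimum, each transcript as its own feature, and leaving out each library in turn. Counting without X- and Y-linked genes was added after the data were seen.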

Results

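RNA was sequenced from mouse splenic B cells labelled wild-type (WT) or Chd4 knockout (KO). CHD4 is an ATP-dependent chromatin remodeller and a core enzyme of the nucleosome remodelling and deacetylase (NuRD) complex. Cells were taken unstimulated (0 hr) or after 48 hr with 10 µg/ml lipopolysaccharide (LPS), a bacterial activator of B cells, and 25 ng/ml interleukin 4 (IL-4), a cytokine that directs switching to IgG1 and IgE. The 12 libraries formed 4 groups of 3: WT 0 hr (replicates 1 to 3), KO 0 hr (4 to 6), WT 48 hr (7 to 9) and KO 48 hr (10 to 12). Estimated counts per library totalled 39 M to 53.2 M, with a median of 51.1 M, and 19125 genes were tested. Between-replicate variation, as edgeR's biological coefficient of variation, was 17.7% in WT 0 hr and 14.3% in WT 48 hr, against 31.1% in KO 0 hr and 23.9% in KO 48 hr. On the second principal component, with 6.5% of the variance, KO 0 hr replicate 6 (9.7) and KO 48 hr replicate 12 (6.6) lay toward the WT libraries (15.3 to 37.4), and the other KO libraries lay at -23.9 or below.

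The targeted gene was examined in every library as a check of the labels. Chd4 (chromosome 6, 125095981 to 125130591 in mm10) was at 86.8 ± 16.5 CPM (SD, n = 3) in WT 0 hr and 87.8 ± 15.3 CPM in libraries labelled KO at 0 hr. Its log2 fold change there was 0.02 (SE 0.22, 95% interval -0.45 to 0.48, edgeR adjusted p = 0.99). At 48 hr Chd4 fell from 107 ± 14.3 to 54.9 ± 18.2 CPM (n = 3 each), a log2 fold change of -0.96 (SE 0.22, 95% interval -1.43 to -0.49, adjusted p = 0.038). The libraries labelled KO held 51.3, 38.8 and 74.7 CPM at 48 hr and 100, 70.6 and 92.8 CPM at 0 hr, so the level of Chd4 RNA did not set the labels apart at 0 hr. KO and WT below mean libraries labelled so, and a direction at 0 hr is a direction between labels that Chd4 RNA did not support. The difference between the 48 hr and the 0 hr effect was -0.98 (SE 0.31, 95% interval -1.64 to -0.32, edgeR adjusted p = 0.35). The 48 hr call ended, with adjusted p from 0.055 to 0.16, when WT 0 hr replicate 1 (0.055) or 3 (0.06), WT 48 hr replicate 7 (0.096), 8 (0.076) or 9 (0.12), or KO 48 hr replicate 10 (0.16) or 11 (0.13) was left out. Counts cover the whole transcript, and the position of the deleted part was not given in the sources used here, so reads outside it would still be counted.

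Among the 14 tested NuRD partner genes, 0 of 14 passed the edgeR test between genotypes at 0 hr, both over all genes and adjusted over the list alone (1 at an unadjusted p below 0.05, and 0 by DESeq2, limma-voom or the likelihood ratio test). The histone deacetylases Hdac1 (173 CPM in WT, 179 in KO) and Hdac2 (67.0 and 72.2 CPM) had log2 fold changes of 0.05 and 0.11 at 0 hr, with adjusted p = 0.94 and 0.83. At 48 hr 1 of 14 rose, Chd5, a neuronal relative of Chd4, which had 1 estimated count over the 3 WT libraries and 93 over the 3 KO libraries. That ratio was 91.3 (exact 95% interval 16 to 3650, adjusted p = 0.046), and the call was lost in 11 of 12 fits that left out 1 library, all but the fit without KO 48 hr replicate 12.

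**Figure D1:**
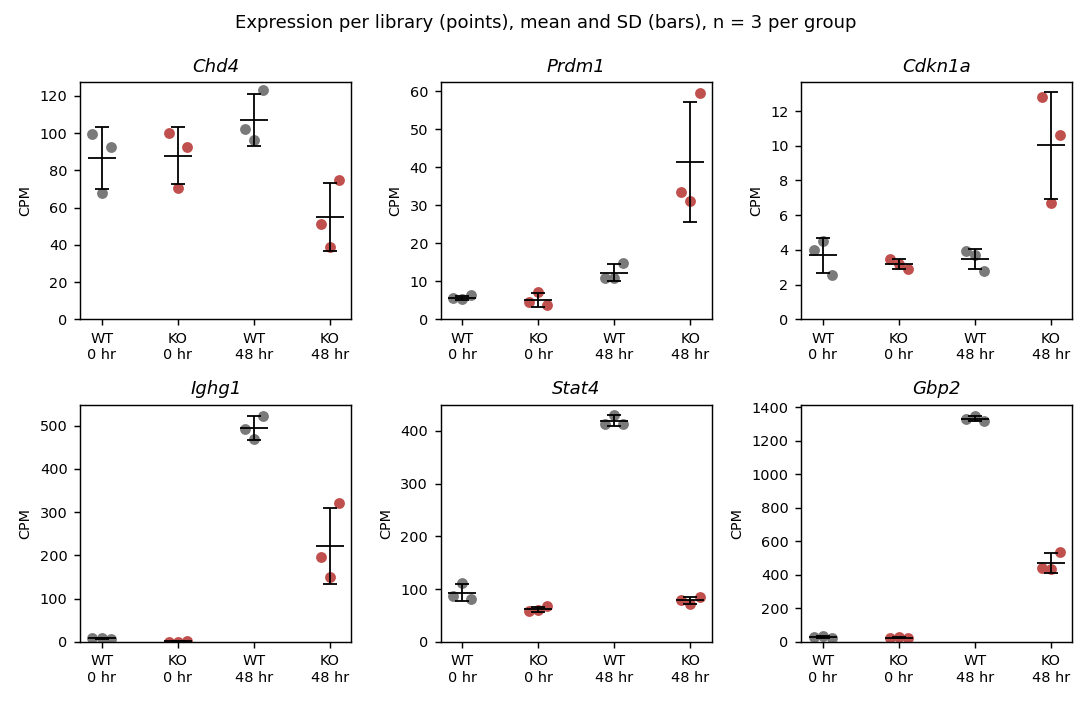
CPM (linear axis) of Chd4, Prdm1, Cdkn1a, Ighg1, Stat4 and Gbp2 in each library (points), with group mean and SD (bars, n = 3) for WT (grey) and KO (red) at 0 hr and 48 hr. Stat4 was at 420 ± 9.82 CPM in WT 48 hr and 78.5 ± 7.09 CPM in KO 48 hr, while Chd4 was at 86.8 and 87.8 CPM in WT and KO at 0 hr.

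Xist and Y-linked transcripts separated the genotypes as well. Xist, the RNA that coats the inactive X chromosome of female cells, was at 259 ± 38.4 CPM in WT 0 hr and 1.57 ± 0.0167 CPM in KO 0 hr (n = 3 each), and at 78.7 ± 4.41 and 0.94 ± 0.0756 CPM at 48 hr (log2 fold changes -7.37 and -6.38, edgeR adjusted p = 2.5e-12 and 2.1e-11). The Y-linked helicase gene Ddx3y was at 26.0 ± 2.45 CPM in WT 0 hr and 120 ± 24.9 CPM in KO 0 hr. It was at 21.4 ± 0.552 and 117 ± 10.3 CPM at 48 hr. Across Ddx3y, Uty, Kdm5d and Eif2s3y, the WT level was 20.3% to 33.0% of the KO level at 0 hr and 16.2% to 21.1% at 48 hr. Genotype and sex-linked expression therefore moved together in all 12 libraries, and every comparison of KO with WT below carries that difference. The library kit does not mark strand, so reads of Xist and its antisense partner Tsix cannot be told apart.

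**Figure D2:**
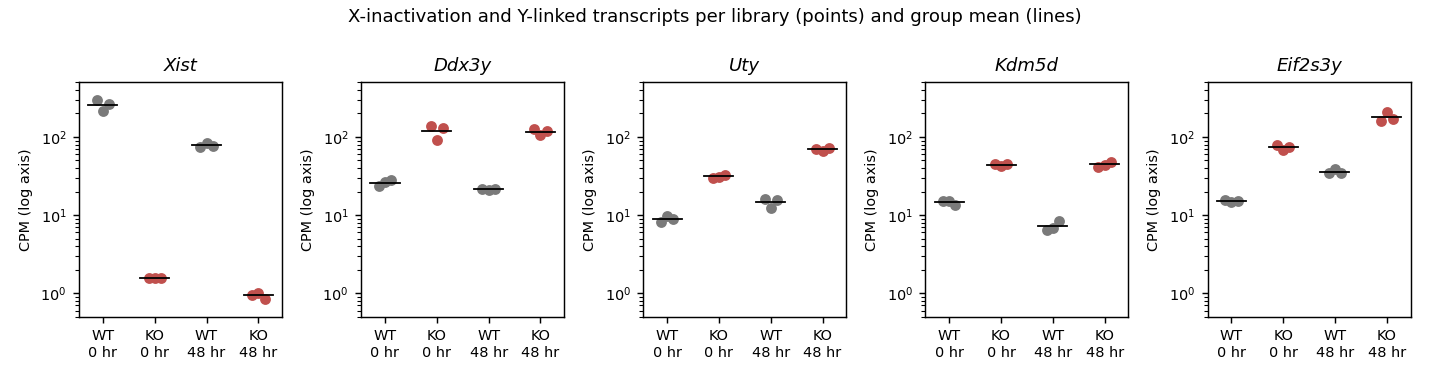
CPM on a log axis of Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y in each library (points) with the group mean (lines) for WT (grey) and KO (red). Xist averaged 259 and 78.7 CPM in WT and 1.57 and 0.94 CPM in KO at 0 hr and 48 hr, and Ddx3y averaged 26.0 and 21.4 CPM in WT and 120 and 117 CPM in KO.

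The comparison of KO with WT at 0 hr asks what differs between unstimulated libraries labelled KO and WT. Ighg1 (chromosome 12, 113325240 to 113330523), the IgG1 constant region, fell from 8.57 ± 1.19 to 0.695 ± 0.351 CPM (SD, n = 3; log2 fold change -3.59, SE 0.33, edgeR adjusted p = 5.1e-05). The interferon-inducible GTPase Iigp1 fell by 2.39 on the log2 scale (5.45 ± 0.814 to 1.04 ± 0.165 CPM, adjusted p = 0.00011). Cxcr3, a chemokine receptor of T-bet-positive lymphocytes, fell by 2.37 (21.2 ± 6.23 to 4.10 ± 2.27 CPM, adjusted p = 0.0062), and the protease inhibitor gene Serpina3f fell by 2.70 (adjusted p = 0.00013). Among genes that rose, the RNA-binding protein gene Rbm45 (chromosome 2, 76369984 to 76383768) went from 3.74 ± 0.418 to 33.9 ± 5.00 CPM (log2 fold change 3.18, SE 0.15, adjusted p = 1.1e-07). Rapgef3, an exchange factor activated by cyclic AMP, rose from 3.09 ± 0.61 to 24.3 ± 3.70 CPM (log2 fold change 2.97, adjusted p = 3.8e-05). Each of these 6 kept its call with any library left out. Serpina3 genes and heavy-chain constant regions are gene families with some similar members, so the split of reads among similar members is uncertain.

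Standing genes of B cell activation and identity were also read at 0 hr. Prdm1 (log2 fold change -0.16, edgeR adjusted p = 0.93), Irf4 (0.26, adjusted p = 0.79) and Mki67 (0.30, adjusted p = 0.55) did not pass the test, nor did Xbp1, Bcl6, Pax5, Cdkn1a or Myc.

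Among gene lists at 0 hr, marginal zone B cell genes had the lowest camera p. Of 13 tested, 5 rose and 0 fell (11 rose when adjusted over the list alone), with a median log2 fold change of 0.77 (camera adjusted p = 7.87e-15, adjusted p = 0.0882 with an estimated correlation). The semaphorin receptor gene Plxnd1 rose by 2.43 on the log2 scale (5.41 ± 2.88 to 29.1 ± 12.6 CPM, n = 3, edgeR adjusted p = 0.0046). Cd1d1, a lipid-presenting molecule high on marginal zone cells, rose by 0.65 (72.6 ± 3.49 to 114 ± 7.57 CPM, adjusted p = 0.01). The tetraspanin gene Cd9 rose by 0.92 (adjusted p = 0.022) and lies 364 kb from Chd4 on chromosome 6. Interferon-response genes had 3 of 33 lower and 0 higher (7 lower adjusted over the list alone, median -0.28, camera adjusted p = 2.53e-13, adjusted p = 0.213 with an estimated correlation). They included Iigp1 and the chemokine Cxcl10 (-1.62, adjusted p = 0.015). The Cd1d1 call ended without WT 0 hr replicate 1 (adjusted p = 0.061), and Cxcl10 without WT 0 hr replicate 2 (0.062) or KO 0 hr replicate 4 (0.052). That of Cd9 ended without WT 0 hr replicate 1 (0.12) or 3 (0.11), KO 0 hr replicate 4 (0.056) or 5 (0.075) or WT 48 hr replicate 7 (0.051). The number of marginal zone members called fell from 5 to 1 without WT 0 hr replicate 1, to 2 without WT 0 hr replicate 3, KO 0 hr replicate 4 or 5 or WT 48 hr replicate 7, to 3 without WT 48 hr replicate 9, and to 0 in a fit of the 6 libraries at 0 hr. For interferon genes it went from 3 to 2 without WT 0 hr replicate 2, to 5 without KO 48 hr replicate 12, and to 1 in that 6-library fit.

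The plasma cell list had 2 of 20 higher at 0 hr, the BAFF and APRIL receptor gene Tnfrsf13b and Sdc1, which encodes syndecan-1 (6 higher and 1 lower adjusted over the list alone, median 0.19, camera adjusted p = 0.00869, adjusted p = 0.575 with an estimated correlation). Without KO 0 hr replicate 5 this list's adjusted p was 0.27. Its 2 called members became 0 without WT 0 hr replicate 1 or 3, and 1 without WT 0 hr replicate 2, KO 0 hr replicate 5, any WT 48 hr library or KO 48 hr replicate 10 or 11. In 4 more lists camera put KO lower although 0 members passed over all genes: germinal center B cells (0 of 11, median -1.17, adjusted p = 6.22e-05), mitosis (0 of 25, -0.21, 0.000107), replication-dependent histones (0 of 16, -0.39, 0.000545) and IL-4 and STAT6 targets (0 of 10, -0.34, 0.00149). Adjusted over the list alone, 3, 1, 0 and 4 of their members were lower, and by edgeR 8, 5, 3 and 5 had an unadjusted p below 0.05. DESeq2 called 2, 2, 0 and 3 of them, the likelihood ratio test 0, 2, 0 and 3, and limma-voom 0 in each. With an estimated correlation the adjusted p was 0.514, 0.575, 0.635 and 0.46, and the histone value was 0.2 without KO 0 hr replicate 5. Marker lists of T cells, NK cells, monocytes, erythroid cells and 6 other non-B lineages were not called at 0 hr. Their medians included 0.46, 0.48, 0.47 and 1.11 in that order (camera adjusted p = 0.0831, 0.0821, 0.162 and 0.251), and the T cell kinase gene Zap70 was the only member called by edgeR's quasi-likelihood test (log2 fold change 2.04, adjusted p = 0.041, lost in 10 of 12 fits that left out 1 library). DESeq2 also called 1 of 10 NK cell genes.

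In all, 212 of 19125 genes differed at 0 hr, 130 higher and 82 lower in KO (edgeR quasi-likelihood, adjusted p below 0.05). The count was 107, 137 and 79 without WT 0 hr replicate 1, 2 and 3, 135 without WT 48 hr replicate 7, 426 without KO 0 hr replicate 6, and 75 in the 6-library fit. Of 32 named calls, 18 kept their call with each library left out in turn. DESeq2 called 632 genes and edgeR's likelihood ratio test 547. The share of calls higher in KO was 61.3%, and 50.5% to 68.3% over all settings.

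The comparison at 48 hr asks what differs between the labels in B cells activated to divide and switch. Libraries labelled KO had lower Stat4, Gbp2 and Gbp2b and higher Prdm1. Stat4 (chromosome 1, 51987148 to 52107189), a signal transducer of interleukin 12 and type I interferon, fell from 420 ± 9.82 to 78.5 ± 7.09 CPM (SD, n = 3; log2 fold change -2.42, SE 0.13, edgeR adjusted p = 1.5e-07). Gbp2 (chromosome 3, 142620602 to 142638008), an interferon-inducible GTPase of cell-autonomous defence, fell from 1330 ± 15.3 to 470 ± 58.1 CPM (-1.50, adjusted p = 4.2e-05). Its neighbouring paralog Gbp2b fell from 82.8 ± 4.84 to 19.1 ± 4.22 CPM (-2.12, adjusted p = 0.005). Prdm1 (chromosome 10, 44437177 to 44528501), which encodes the plasma cell regulator BLIMP-1, rose from 12.3 ± 2.25 to 41.3 ± 15.8 CPM (log2 fold change 1.74, SE 0.27, adjusted p = 0.0048). Without WT 48 hr replicate 7 the Prdm1 call ended (1.63, adjusted p = 0.051), and it held in the other 21 settings. Gbp2 and Gbp2b are neighbouring paralogs, so the split of reads between them is uncertain.

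Further genes lower in KO at 48 hr were Serpina3g (943 ± 29.4 to 206 ± 21.4 CPM, log2 fold change -2.19, edgeR adjusted p = 5e-07), Iigp1 (-2.79, adjusted p = 2.6e-05), the short-chain fatty acid receptor gene Ffar2 (-1.75, adjusted p = 0.00058) and the guanylate cyclase gene Gucy2c (-4.43, adjusted p = 0.0036). Among those higher, Vdr, the vitamin D receptor, rose from 0.675 ± 0.541 to 24.2 ± 11.3 CPM (5.16, adjusted p = 0.0026). Cfap43, a gene of motile cilia, rose from 0.15 ± 0.138 to 17.7 ± 14.7 CPM (6.87, adjusted p = 0.0043). Ccnb1ip1 had 1 estimated count over the 3 WT libraries and 1212 over the 3 KO libraries, a ratio of 1190 (exact 95% interval 213 to 47000, adjusted p = 4.7e-05). All of these held with any library left out, although Cfap43 ranged from 6.11 to 7.54, Vdr from 4.57 to 5.56, Gucy2c from -5.05 to -4.08 and Ccnb1ip1 from 9.33 to 11.98 on the log2 scale. By limma-voom Cfap43 did not pass (6.97, adjusted p = 0.18).

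Batf, an AP-1 family transcription factor, fell in KO at 48 hr from 387 ± 29.5 to 230 ± 21.6 CPM (SD, n = 3; log2 fold change -0.75, edgeR adjusted p = 0.0066). It was the only 1 of 26 class-switch and end-joining genes called, both over all genes and adjusted over the list alone. Ighg1, singled out at 48 hr after its values were seen, fell from 494 ± 27.0 to 222 ± 87.9 CPM (-1.15, adjusted p = 0.033). That call ended without WT 0 hr replicate 1 (0.056) or 3 (0.051), any WT 48 hr library (0.09 to 0.11), or KO 48 hr replicate 10 (0.16) or 11 (0.13). Ighe, of the IgE constant region and also singled out afterwards, was at 32.2 and 61.2 CPM (0.93, adjusted p = 0.51). Its KO libraries disagreed, with 79.2, 81.9 and 22.5 CPM in replicates 10, 11 and 12. The WT 48 hr libraries held 33.1, 34.2 and 29.4 CPM.

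Plasma cell genes had the lowest camera p at 48 hr. Of 20, 6 rose and 0 fell (12 rose adjusted over the list alone), with a median log2 fold change of 0.66 (camera adjusted p = 6.46e-12, adjusted p = 0.0969 with an estimated correlation). Besides Prdm1, Zbtb20, a zinc-finger factor of long-lived plasma cells, rose from 32.9 ± 0.877 to 59.7 ± 9.42 CPM (0.86, edgeR adjusted p = 0.0036). Derl3, of endoplasmic reticulum degradation, rose from 11.5 ± 0.773 to 22.9 ± 2.05 CPM (1.00, adjusted p = 0.023). Irf4 (80.8 ± 9.47 and 137 ± 23.6 CPM, log2 fold change 0.76, adjusted p = 0.094) and Xbp1 (541 ± 3.67 and 644 ± 72.9 CPM, 0.25, adjusted p = 0.36) did not pass. The plasma cell count fell to 1 member without WT 48 hr replicate 7 and to 2 without WT 48 hr replicate 8 or 9 or KO 48 hr replicate 10 or 11, and was 9 without KO 0 hr replicate 4. Unfolded-protein-response genes had 3 of 23 higher (4 higher and 1 lower adjusted over the list alone, median 0.24, camera adjusted p = 7.54e-05, adjusted p = 0.513 with an estimated correlation). They included the chaperone gene Hsp90b1 (2440 ± 65.1 to 3750 ± 141 CPM, 0.62, adjusted p = 0.004). Their count was 0 without WT 48 hr replicate 7 and 1 without WT 48 hr replicate 8 or 9 or KO 48 hr replicate 10 or 11.

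Targets of p53 had 3 of 25 higher and 0 lower at 48 hr (8 higher adjusted over the list alone, median 0.29, camera adjusted p = 0.000132, adjusted p = 0.186 with an estimated correlation). They were the cell-cycle inhibitor Cdkn1a (3.48 ± 0.603 to 10.0 ± 3.08 CPM, log2 fold change 1.53, edgeR adjusted p = 0.014), the BH3-only gene Pmaip1 (51.5 ± 4.43 to 80.5 ± 3.31 CPM, 0.64, adjusted p = 0.023) and Phlda3 (2.26, adjusted p = 0.046). The number of p53 targets called was 0 without WT 48 hr replicate 7, 8 or 9 or KO 48 hr replicate 10, 1 without KO 48 hr replicate 11, 2 without WT 0 hr replicate 2 or 3 or KO 0 hr replicate 4, and 5 without KO 0 hr replicate 6. Mitosis genes had 0 of 25 called by edgeR (1 higher adjusted over the list alone, 2 at an unadjusted p below 0.05, 1 by DESeq2, 0 by limma-voom), with Mki67, a marker of dividing cells, at 221 ± 29.1 and 336 ± 23.9 CPM (0.60, adjusted p = 0.07). DNA replication genes had 0 of 28 called (1 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom).

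Interferon-response genes had 3 of 33 lower and 0 higher at 48 hr (3 lower adjusted over the list alone, median -0.23, camera adjusted p = 9.8e-07, adjusted p = 0.293 with an estimated correlation). These were Iigp1, Gbp2 and Gbp3 (792 ± 13.5 to 398 ± 16.7 CPM, log2 fold change -0.99, edgeR adjusted p = 0.0023), and the count was 3 in each fit that left out 1 library except 6 without KO 48 hr replicate 12. The classical type I interferon genes Ifit1 and Isg15 were not among those 3, which with 3 libraries per group does not show that they were unchanged. DESeq2 called 5 members lower. Marginal zone genes had 3 of 13 higher (5 adjusted over the list alone, median 0.57, camera adjusted p = 7.54e-05, adjusted p = 0.293 with an estimated correlation): the scavenger receptor Cd36 (50.9 ± 4.41 to 251 ± 132 CPM, 2.30, adjusted p = 0.0061), Cd9 (1.13, adjusted p = 0.005) and Cd1d1 (0.59, adjusted p = 0.024). That count was 0 without WT 48 hr replicate 7, 1 without WT 48 hr replicate 9 and 2 without WT 48 hr replicate 8 or KO 48 hr replicate 10 or 11. IL-4 and STAT6 targets had 1 of 10 lower, Batf (1 adjusted over the list alone, median -0.49, camera adjusted p = 0.000132, adjusted p = 0.242 with an estimated correlation), and 4 of 10 without KO 48 hr replicate 12.

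Germinal center genes had 1 of 11 higher at 48 hr, the transcription factor Mef2b (41.5 ± 3.21 to 80.9 ± 16.1 CPM, log2 fold change 0.96, edgeR adjusted p = 0.0039; 4 adjusted over the list alone, list median 0.83, camera adjusted p = 0.000403, adjusted p = 0.513 with an estimated correlation). That count was 2 without any KO 0 hr library or KO 48 hr replicate 12, and 1 was lower without KO 0 hr replicate 6. Early B progenitor genes had 2 of 6 higher, Kit and Sox4 (3 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.268 with an estimated correlation). Both calls were lost without any WT 0 hr library, WT 48 hr replicate 8 or 9, or KO 48 hr replicate 10 or 11, where 0 members were called, and 1 was called without KO 0 hr replicate 4 or WT 48 hr replicate 7. Ribosomal protein genes (0 of 20, median -0.18, camera adjusted p = 0.0159), striated muscle genes (1 of 10 higher, 0.0258) and T-bet-positive B cell genes (1 of 6 lower, Cxcr3, 0.0428) had adjusted p of 0.941, 0.642 and 0.642 with an estimated correlation. Each of these 3 lost its call without at least 3 of the libraries in turn, with adjusted p up to 0.12, 0.16 and 0.2. Adjusted over the list alone 0, 2 and 2 of their members were called. No marker list of T cells, NK cells, monocytes, neutrophils, dendritic cells, erythroid cells, platelets, stroma or neurons was called at 48 hr, with camera adjusted p from 0.209 to 0.991, although by edgeR 1 NK member (Prf1, adjusted p = 0.022) and 1 neuronal member (Map2, adjusted p = 0.038) rose. In the lists with 0 edgeR calls, DESeq2 called 3 T cell, 1 dendritic cell, 2 platelet and 1 stromal gene. The Prf1 and Map2 calls ended without any WT 48 hr library or KO 48 hr replicate 10 or 11, and Map2 also without any WT 0 hr library.

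At 48 hr 386 of 19125 genes differed, 282 higher and 104 lower in KO (edgeR, adjusted p below 0.05). The count was 136, 141 and 152 without WT 48 hr replicate 7, 8 and 9, 146 and 144 without KO 48 hr replicate 10 and 11, and 1080 without KO 48 hr replicate 12. Of 52 named calls, 22 kept their call with each library left out in turn. DESeq2 called 1052 genes (585 higher and 467 lower), the likelihood ratio test 1000 (705 and 295) and limma-voom 193 (110 and 83). With relative log expression factors the split was 238 and 135. The share higher in KO was 73.1%, and 55.6% to 74% over all settings.

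**Figure D3:**
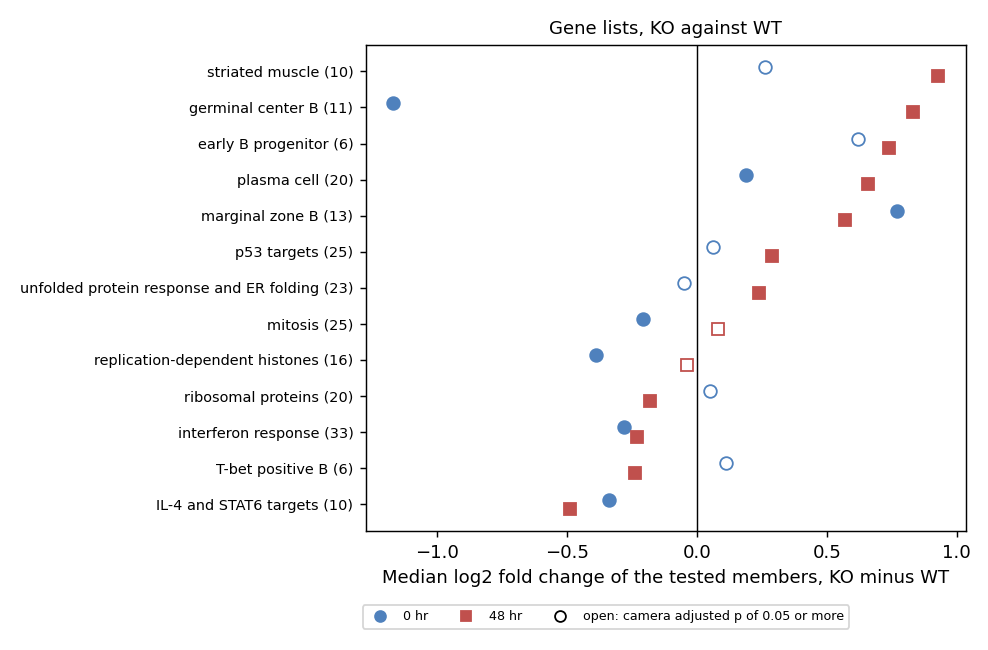
Median log2 fold change (KO minus WT) of the tested members of each gene list called by camera at 0 hr (circles) or 48 hr (squares), with the number of members in parentheses and open symbols where camera's adjusted p was 0.05 or more. Plasma cell genes lay at 0.19 and 0.66 and interferon-response genes at -0.28 and -0.23 at 0 hr and 48 hr.

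Whether the same genes changed in both states was tested by the overlap of the calls, which come from separate libraries. The labels do not say whether the cells of both times came from the same animals. The sex-linked difference recurred at both times, and a difference between animals would too if they were shared. The p-values of the overlap therefore do not show independent effects of the knockout. Higher at both times were 49 genes, against 1.9 expected for independent lists (one-sided Fisher's exact test, p = 1.6e-56), and lower at both times were 23, against 0.45 (p = 6.3e-34). They included Rbm45, which rose by 3.57 on the log2 scale at 48 hr, Cd9 and Cd1d1 among the genes that rose, and Iigp1, Cxcr3, Serpina3f and Ighg1 among those that fell. Only 3 genes were called in opposite directions, among them Gbp2b, which rose by 2.71 at 0 hr and fell by 2.12 at 48 hr. Across 19125 genes, which are not independent replicates, the log2 fold changes at the 2 times correlated with r = 0.30. The 72 shared calls became 42 without WT 0 hr replicate 3, 126 without KO 48 hr replicate 12 and 43 with 6-library fits.

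The interaction asks whether the difference between libraries labelled KO and WT was itself different in unstimulated and stimulated cells. Stat4 had the smallest p: it rose from 93.3 ± 15.4 to 420 ± 9.82 CPM (SD, n = 3) over 48 hr in WT and was at 61.8 ± 4.97 and 78.5 ± 7.09 CPM in KO (difference of log2 fold changes -1.82, SE 0.17, edgeR adjusted p = 0.0013). Gbp2b (0.612 ± 0.409 to 82.8 ± 4.84 CPM in WT, 3.97 ± 1.71 to 19.1 ± 4.22 CPM in KO) had a difference of -4.83 (adjusted p = 0.0027). The membrane protein gene Shisa8, at 3.78 and 12.2 CPM in WT and KO at 0 hr and at 125 and 111 CPM at 48 hr, had -1.87 (adjusted p = 0.0027). These 3 kept their call with any library left out. Gbp2 (-1.26, adjusted p = 0.028), Ighg1 (2.43, adjusted p = 0.044) and Mef2b (1.30, adjusted p = 0.029) were also called, and each lost its call in 7 or more of the 12 fits that left out 1 library, with adjusted p up to 0.13, 0.18 and 0.15. Prdm1 (1.90, adjusted p = 0.1) and Cdkn1a (1.73, adjusted p = 0.14) did not pass.

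By gene list, germinal center B cell genes had the lowest camera p in the interaction, with 1 of 11 higher (7 adjusted over the list alone, median 1.44, camera adjusted p = 6.84e-12, adjusted p = 0.19 with an estimated correlation). In total 22 genes were called, 13 with a positive and 9 with a negative difference, against 1646 genes at an unadjusted p below 0.05. That count was 3 without WT 48 hr replicate 7 (0 positive) and 90 without KO 48 hr replicate 12 (62 positive), and DESeq2 gave 219 (116 positive). Of 18 named calls, 3 kept their call in each of the 12 fits.

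The response of WT cells to 48 hr of LPS and IL-4 was also measured. All 25 mitosis genes rose, with a median log2 fold change of 4.46 (camera adjusted p = 1.39e-41, adjusted p = 0.00229 with an estimated correlation), among them the kinase gene Plk1 (8.66 ± 0.437 to 230 ± 16.5 CPM, SD, n = 3, edgeR adjusted p = 1.5e-11). DNA replication genes had 27 of 28 higher (median 3.55, adjusted p = 0.00146 with an estimated correlation), and ribosome biogenesis genes 23 of 23 (median 2.38, adjusted p = 0.00229 with an estimated correlation). Xbp1 rose by 1.90 on the log2 scale and Myc by 1.80 (adjusted p = 8e-09 and 9.6e-09). Il6 rose from 0.138 ± 0.111 to 51.4 ± 5.21 CPM, and the cytokine signalling inhibitor Cish from 0.836 ± 0.291 to 167 ± 3.94 CPM. Bcl6, a germinal center repressor, fell by 3.29, and Pax5, a B cell identity factor, by 1.48 (adjusted p = 3.5e-07 and 3.1e-06). The counts adjusted over the list alone were 25, 27 and 23 for these 3 lists.

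These were the 3 lists that held with an estimated correlation. Further lists with a camera call in WT cells over time were cholesterol synthesis (21 of 21 higher), nuclear-encoded oxidative phosphorylation (24 of 24), ribosomal proteins (20 of 20), glycolysis (17 of 18, 1 lower), the unfolded protein response (19 of 23), the amino acid response (15 of 20, 3 lower), NF-kB targets (18 of 24, 1 lower), interferon response (27 of 33, 1 lower), class switch and end joining (19 of 26, 4 lower), IL-4 and STAT6 targets (8 of 10), histones (12 of 16), apoptosis (14 of 22, 5 lower) and NuRD partners (9 of 14). The apoptosis call ended without KO 0 hr replicate 4 (adjusted p = 0.052). NuRD partners also had 2 lower, Mta3 (-0.55) and Chd5, whose call ended in 5 of 12 fits that left out 1 library (adjusted p up to 0.097). Their rises included the histone-binding gene Rbbp7 (140 ± 17.7 to 875 ± 14.1 CPM) and Hdac2 (67.0 ± 8.05 to 319 ± 9.21 CPM). Lower lists were resting and recirculation (14 of 18 members, 2 higher), B cell identity (15 of 22, 2 higher), marginal zone (9 of 13, 2 higher), MHC class II (7 of 10), and immediate early and handling stress (11 of 16, 5 higher). Counts adjusted over the list alone were the same for each of these lists. With an estimated correlation their adjusted p ranged from 0.0784 to 0.387.

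The marker lists of non-B cells that had a camera call were lower at 48 hr. Lower were 14 of 15 monocyte and macrophage, 11 of 12 neutrophil and 13 of 17 T cell genes (1 T cell gene higher). So were 7 of 7 erythroid, 5 of 6 platelet and 10 of 13 neuronal genes, with the same counts adjusted over the list alone. The camera adjusted p of these lists ranged from 0.000784 to 0.0477, and from 0.285 to 0.507 with an estimated correlation. The T cell call ended without WT 0 hr replicate 2, KO 0 hr replicate 4 or WT 48 hr replicate 7 or 9 (adjusted p 0.05 to 0.069), and the neutrophil call without WT 0 hr replicate 2 or KO 0 hr replicate 4 (0.05 and 0.052). Hemoglobin Hba-a2 went from 430 ± 94.1 to 2.27 ± 0.61 CPM (n = 3, edgeR adjusted p = 3.8e-06). The prostaglandin dehydrogenase gene Hpgd had 1091 estimated counts over the WT 0 hr libraries and 0 over the WT 48 hr libraries, which makes it at least 254-fold lower against a floor of 3 counts over the group. Heat-shock gene Hspa1b, on the handling stress list, went from 880 ± 172 to 2.81 ± 0.754 CPM (adjusted p = 9.9e-11).

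In WT cells 14138 genes changed over 48 hr, 6311 higher and 7827 lower (edgeR, adjusted p below 0.05). With upper-quartile scaling the split was 4180 higher and 10944 lower. The median log2 fold change of all genes was -0.39, and -0.29 with relative log expression and -1.06 with upper-quartile scaling, so changes over time stand relative to that median. Irf4 (0.66, adjusted p = 0.013) and Prdm1 (1.11, adjusted p = 0.0025) were at -0.02 and 0.43 with upper-quartile scaling (adjusted p = 0.94 and 0.16). The same comparison in libraries labelled KO asks whether they respond alike: 13517 genes changed, 6311 higher and 7206 lower (4231 and 10481 with upper-quartile scaling). Called in both genotypes were 5808 genes higher in both, 6383 lower in both and 19 in opposite directions. Chd4 itself fell over time in KO (-0.68, adjusted p = 0.013), while in WT its log2 fold change was 0.30 (adjusted p = 0.21).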

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

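The tests of a deleted segment, of swapped labels, of index hopping and of sex as a cause were chosen after the result was seen, as were the count of calls near Chd4 and the position test on time genes. The genes and gene lists given after the 3 patterns were picked out by the test of the difference between 0 hr and 48 hr itself. Chd4 is weighed as the targeted gene, and its difference did not pass adjustment over all genes (0.35). The separation by Xist and Y-linked genes and the shared calls were alike at both times and bear on every comparison of KO with WT.

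Chd4 RNA was lower at 48 hr and not at 0 hr in libraries labelled KO, with a difference of log2 fold changes of -0.98 (SE 0.31, edgeR adjusted p = 0.35, 0.063 to 0.62 over the alternatives). A deleted segment with the rest of the transcript still counted would lower the counts alike at both times. The 95% interval of the difference ended at -0.32, but that interval is the observation itself and did not pass adjustment, so a deleted segment stays open. Swapped WT and KO labels at 0 hr would put WT levels of Xist in libraries labelled KO, and 0 of them reached the lowest WT library. Xist marks the sex of the cells and not the Chd4 genotype. That test holds only if each genotype had the same sex at both times, which the labels do not say. Xist alone therefore cannot exclude a swap. A later loss of the RNA, a mixture of deleted and undeleted cells and a difference in the RNA made from the deleted allele were not tested and stay open.

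Xist and Y-linked genes separated the genotypes in all 12 libraries. Index hopping as the source of Y-linked counts in WT would bring Xist into KO libraries to a like share, and the median Y-linked share in WT at 48 hr (19.3%) was 16.1 times the Xist share in KO (1.19%), which argues against it. If WT libraries held mostly female cells and KO libraries male cells, genes that escape X inactivation would be lower in KO. Their median log2 fold change was -0.49 at 0 hr and -0.41 at 48 hr, with 4 of 5 genes negative each time. By edgeR, Kdm6a (adjusted p = 0.037 and 0.026) and Eif2s3x (0.0078 and 0.0098) passed at 0 hr and 48 hr. Kdm5c, Pbdc1 and Ddx3x passed at neither time. The direction is that of such a difference in sex, carried mainly by the genes that passed. Since 0 genotypes held both high- and low-Xist libraries, effects of sex and of the knockout on autosomal genes cannot be told apart, and the origin of the Y-linked reads in WT stays open.

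Many calls were shared between the times, 72 in the same direction. A difference in library scaling would move the shared calls with the scaling, and at least 71 were shared under the 2 other scalings. Chromosome segments of another strain could place calls next to each other. All placed autosomal calls of each time were counted, not the shared calls alone. At 0 hr 65 of 183 lay within 1 Mb of another (45.5 in 10000 shuffles, permutation p = 0.0095). At 48 hr 157 of 346 did (138, permutation p = 0.048). The same numbers of the strongest time genes gave 57 and 158 (permutation p = 0.079 and 0.04), so a strain segment cannot be told apart from the ordinary clustering of genes. Within 2 Mb of Chd4, 3 of 58 genes were called at both times, Ncapd2, Mrpl51 and Cd9 (one-sided Fisher's exact test, p = 0.029 at 0 hr and 0.13 at 48 hr). Calls farther from Chd4 were not counted, so a longer segment around it was not tested.

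Other genes with a difference between the times (log2) were Basp1 3.07, Rassf6 2.84, Ryr2 2.65, Ighg1 2.43, Ulbp1 1.69, Tmem87a 1.46, Arrdc3 1.39, Atp10d 1.34 and Mef2b 1.30. Negative differences were found for Gbp2b -4.83, Shisa8 -1.87, Stat4 -1.82, Ffar2 -1.79, Eps8 -1.54, Fam129c -1.28, Gbp2 -1.26 and Akr7a5 -1.10. Of these, Gbp2b, Shisa8 and Stat4 kept their call with any library left out.

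Gene lists with a difference by camera were germinal center B cells (adjusted p = 6.84e-12), the unfolded protein response (1.63e-08), mitosis (3.47e-06), p53 targets (0.000158), plasma cells (0.000247), replication-dependent histones (0.00557) and neutrophils (0.0483), each more positive at 48 hr. Ribosomal proteins (0.00619), oxidative phosphorylation (0.0307) and marginal zone B cells (0.0483) were more negative. With an estimated correlation all 10 had an adjusted p from 0.19 to 0.984. Histones lost their call without KO 0 hr replicate 5 (0.41), ribosomal proteins without WT 0 hr replicate 3 (0.41), KO 0 hr replicate 4 (0.4) or KO 48 hr replicate 12 (0.057), and oxidative phosphorylation without WT 0 hr replicate 3 (0.39), KO 0 hr replicate 4 (0.15) or 6 (0.11) or KO 48 hr replicate 12 (0.18). Neutrophil genes lost it without WT 0 hr replicate 1 (0.058), KO 0 hr replicate 4 (0.053) or 6 (0.58) or KO 48 hr replicate 11 (0.12). Marginal zone genes lost it without WT 0 hr replicate 1 (0.19) or 3 (0.11), KO 0 hr replicate 5 (0.41), WT 48 hr replicate 7 (0.096) or 9 (0.095), or KO 48 hr replicate 11 (0.065) or 12 (0.093).

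The 6 libraries of each contrast can be split in 10 ways, the real one included, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many calls: 212 at 0 hr (highest other 1), 386 at 48 hr (1), 14138 over time in WT (1) and 13517 over time in KO (0). The other splits put libraries of both groups together. A real difference then adds to the spread within groups and lowers their counts, so these low counts do not measure support for the real ones. For the interaction 60 splits were drawn, and 1 of 60, the real one, gave 22 calls or more (highest other 18). These splits mix the genotypes within each time, which also breaks up the differences that both times share. They therefore cannot tell whether chance gave the interaction count.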

How the results depend on the processing

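Counting without X- and Y-linked genes was chosen after the data were seen; it gave 198 genes at 0 hr, 366 at 48 hr, 21 in the interaction and 62 shared. No paired analysis was run, because each replicate number belongs to 1 library and the labels do not link libraries across times. With DESeq2, 632 genes were called at 0 hr, 1052 at 48 hr and 219 in the interaction, and 184 were shared. With the likelihood ratio test these were 547, 1000, 184 and 171. Limma-voom called 193 at 48 hr. Fits of 6 libraries gave 75 at 0 hr and 43 shared. A 2-fold minimum gave 130 at 0 hr. With each transcript as its own feature, which tests other units, 83, 125 and 3 were called at 0 hr, 48 hr and in the interaction. Without a low-count filter Chd4 at 48 hr was at -0.96 (adjusted p = 0.05) and 15 lists were called at 0 hr. With an estimated correlation 0 lists were called at 0 hr, 0 at 48 hr, 0 in the interaction and 3 over time in WT, against 7, 11, 10 and 27 by camera's preset; fry called 2, 2, 0 and 37. With upper-quartile scaling Irf4 over time in WT lost its call, at -0.02 (adjusted p = 0.94). That scaling moved the median of all genes from -0.39 to -1.06, so the sign of Irf4 there is not a reversal. Apart from fewer libraries or other units, the cause was not tested.

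With 1 library left out, which leaves 2 in its group and assumes a spread shared with the others, the count ran from 79 (without WT 0 hr replicate 3) to 426 (KO 0 hr replicate 6) at 0 hr, also 107 and 137 without WT 0 hr replicate 1 and 2 and 135 without WT 48 hr replicate 7. At 48 hr it ran from 136 (WT 48 hr replicate 7) to 1080 (KO 48 hr replicate 12), with 141, 152, 146 and 144 without replicates 8, 9, 10 and 11. It ran from 13047 to 14345 over time in WT, 12681 to 13671 in KO, 3 (WT 48 hr replicate 7) to 90 (KO 48 hr replicate 12) in the interaction, and 42 (WT 0 hr replicate 3) to 126 (KO 48 hr replicate 12) shared. Chd4 ran from -0.13 to 0.15 at 0 hr and from -1.25 (adjusted p = 0.0035) to -0.81 (0.13) at 48 hr, with the highest adjusted p of 0.16 without KO 48 hr replicate 10. Lists called ran from 7 to 18 (KO 0 hr replicate 6) at 0 hr, 9 to 11 at 48 hr, 7 (WT 0 hr replicate 3) to 17 (WT 0 hr replicate 2) in the interaction and 24 to 28 over time in WT. Of single named results, 276 to 324 were on the same side of the threshold per library left out and 0 to 52 lost a call.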

Other observations

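The genes here were chosen after their values were seen. Trp53 (chromosome 11, 69580359 to 69591873), which encodes the tumour suppressor p53, was higher in KO at 0 hr (39.6 ± 2.18 to 96.6 ± 19.9 CPM, SD, n = 3, log2 fold change 1.29, SE 0.14, edgeR adjusted p = 0.000298) and at 48 hr (59.3 ± 3.47 to 194 ± 23.9 CPM, 1.71, SE 0.14, adjusted p = 1.81e-05). Near Chd4, the condensin subunit gene Ncapd2 had log2 fold changes of 0.84 and 1.13 at 0 hr and 48 hr, and the mitochondrial ribosomal protein gene Mrpl51 of 1.00 and 0.96. Endou, an endoribonuclease gene, was 1.61 and 2.05 higher on the log2 scale.

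Ighd, another heavy-chain constant region, was at a log2 fold change of -0.40 between labels at 0 hr (edgeR adjusted p = 0.56). Over 48 hr in WT, Ighg1 rose by 5.85 and Ighe by 4.82 (6.45 without WT 0 hr replicate 1, which held 2.65 CPM against 0.534 and 0.211), and Igha fell by 4.26 and Ighd by 2.44.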
